A study of Mus musculus with 43 samples.

How the data were processed

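Gene expression was measured by RNA sequencing of whole lung from 43 mice in 7 groups. Per the labels and the study design, the mice were female, 8 to 12 weeks old and of a hybrid 129S6/C57BL/6 background. Mouse Il4, Il33 and the outer part of Il4ra had been replaced with human sequence in the mice used to assess the antibodies. House dust mite extract (HDM) was given into the nose 3 times a week. The design text gives exposures of 4, 15 or 19 weeks, while the labels of these libraries give 11 or 19 weeks, and the labels were used. The groups were saline (n = 5), 11 weeks of HDM (n = 6), 19 weeks of HDM (n = 7), and 19 weeks of HDM with an isotype control antibody (n = 7), with itepekimab, an antibody against IL-33, plus isotype antibody (n = 6), with dupilumab, an antibody against IL-4Rα, plus isotype antibody (n = 7), or with both antibodies (n = 5). The design text names antibody starts at day -3, at 4 weeks and at 11 weeks. The labels do not say which start these libraries had, nor how long saline was given.

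Per the labels' protocols, RNA was extracted with TRIzol and a magnetic bead kit, treated with DNase, and made into strand-specific libraries from 500 ng of RNA with the KAPA stranded mRNA kit and 12 cycles of PCR. Libraries were read as single reads of 33 cycles on an Illumina HiSeq 2000. The deposited table holds expected counts, which are estimated read numbers per NCBI Gene ID: the columns are not scaled to library size, 76.8% of the nonzero values are whole numbers, and the remaining ones carry decimals. Per the submitters' processing notes, the genome build was mm10. The aligner, the counting program and the annotation are not given in the sources used here, nor whether the counting used strand. Near-identical genes and overlapping genes are therefore uncertain.

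The table held 24475 genes, of which 3193 were at 0 in every library. Symbols and positions came from a RefSeq annotation of GRCm38.p6, the assembly that mm10 names. In it 24375 Gene IDs had a symbol and 100 had none. Total counts ran from 11.9 M to 26.7 M per library (M standing for 1e+06). Transcript GC content and length were taken from GENCODE transcripts for 24081 genes.

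Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr by group, which left 15979 genes. Library sizes were scaled with TMM factors. All 43 libraries entered a single quasi-likelihood model with a mean per group (edgeR 4.0.16 in R 4.3.3, robust, residual degrees of freedom 36, biological coefficient of variation 0.431). Contrasts were tested 2-sided with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was called. Standard errors are of the log2 fold change. CPM values are given as mean and SD, and log2 CPM with a prior count of 1. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. Ratios against 1 to 3 counts carry 95% intervals. Bounds and intervals cover counting error only, since PCR copies of a molecule are not independent.

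The 35 gene lists of processes and cell types were tested with camera (limma 3.58.1, preset correlation of 0.01), adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Lists with fewer than 4 measured members, thymus with 3 and immunoglobulin genes, whose symbol pattern matched 1 gene, the helicase gene Ighmbp2, and no immunoglobulin gene, were not tested. A score per mouse summarised the genes called between 19 weeks of HDM and saline, on a scale where the saline mean was 0 and the mean at 19 weeks was 100. It was compared between antibody groups by exact permutation tests. Correlations of responses that share the isotype libraries were set beside simulated unchanged groups and beside splits of the isotype libraries.

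For each contrast the rule for named genes took up to 6 genes per direction with the largest log2 fold change, an adjusted p under 0.05, at least 1 CPM in a group and no overlap between the groups. The last condition was dropped where fewer than 6 genes met it. Immunoglobulin and T cell receptor segments, predicted gene models and IDs without a symbol were left out. The rule also took up to 4 members of each list that passed and a fixed set of type 2 and remodelling genes, and allowed any list member as an example. Groups, tests, lists and this rule were fixed before the data were examined.

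Alternatives fixed at that time were DESeq2 1.42.0, DESeq2 size factors, upper-quartile factors, other filters, the replicate number and the library number as blocks, limma voom with sample weights, fits of the compared groups alone, other control groups, and leaving out each library. Alternatives added after seeing the data were per-library GC and length offsets, the GC slope of each library as a covariate, leaving out the 10 libraries with a GC slope above 0.75, and leaving out 1 gene ID. The GC slope is the slope of a library's log2 expression, relative to the mean of all libraries, on transcript GC content, per 10 percentage points. The procedure was tested on simulated counts for the real genes. For the combination against isotype, on 15882 genes, it recovered 28% of 2-fold, 88% of 4-fold and 94% of 8-fold changes. The simulated counts were drawn independently for each gene, without the differences in GC slope between the real libraries.

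Il4 (highest count 1) and Epx (highest count 24) did not pass the filter. The median counts of Il33 (290) and Il4ra (3702) on the mouse genome do not measure the humanised parts of these genes. The immunoglobulin alternative was not run, since the symbol pattern matched no immunoglobulin gene in the table.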

Results

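RNA sequencing of whole lung was compared between mice given saline, mice exposed to HDM for 11 or 19 weeks, and mice exposed for 19 weeks and treated with antibodies. The 4 antibody groups received isotype control, anti-IL-33 (itepekimab), anti-IL-4Rα (dupilumab) or both, which is called the combination. IL-33 is a cytokine released by epithelium under damage, and IL-4Rα is the receptor chain shared by IL-4 and IL-13. Group sizes were saline n = 5, 11 weeks of HDM n = 6, 19 weeks of HDM n = 7, isotype n = 7, anti-IL-33 n = 6, anti-IL-4Rα n = 7 and combination n = 5. Values below are deposited expected counts, given as CPM with the SD between mice, and log2 fold changes with their standard errors (SE) and adjusted p from edgeR's quasi-likelihood test over 15979 genes. Total counts ranged from 14.0 M to 23.3 M in saline, 13.7 M to 18.2 M at 11 weeks, 11.9 M to 26.7 M at 19 weeks, 16.6 M to 21.8 M with isotype, 14.2 M to 24.3 M with anti-IL-33, 14.9 M to 21.3 M with anti-IL-4Rα and 15.3 M to 19.6 M with the combination.

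The libraries differed along an axis that follows the GC content of transcripts. The first principal component held 61.1% of the variance, and over the 43 libraries it correlated with the GC slope, the tilt of a library towards GC-rich transcripts, at Pearson r = 0.971 and Spearman rho = 0.989 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Without the 2 libraries farthest from the median slope, r was 0.967. Component and slope were computed from the same expression values, so the permutation p is no independent test of their link. Across genes, the weight on the component correlated with GC content at 0.691 and with log transcript length at -0.465. Mean slopes were -0.629 ± 0.177 (SD) in saline, -0.393 ± 0.206 at 11 weeks, 0.135 ± 0.558 at 19 weeks, -0.161 ± 0.274 with isotype, 0.303 ± 0.695 with anti-IL-33, 0.272 ± 0.731 with anti-IL-4Rα and 0.391 ± 0.953 with the combination. Libraries with a slope above 0.75 numbered 2 at 19 weeks, 2 with anti-IL-33, 3 with anti-IL-4Rα, 3 with the combination and 0 in the other groups, and they are called steep below. The slope difference between the combination and isotype was 0.552 and did not pass (exact permutation p = 0.164, adjusted over 4 comparisons 0.219).

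**Figure D1:**
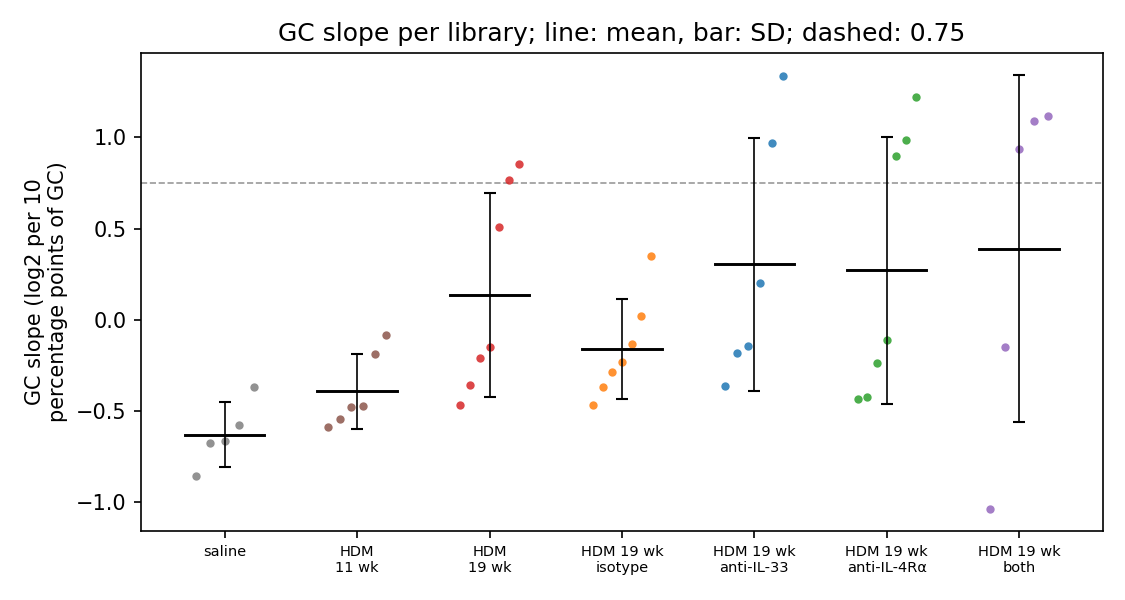
GC slope of each library in log2 units per 10 percentage points of transcript GC content, by group; points are mice, lines means and bars SD, and the dashed line marks 0.75. The 3 steep combination libraries lie between 0.934 and 1.12, and 1 combination library lies at -1.04.

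Exposure to HDM for 11 weeks was compared with saline to describe the disease before the late stage. Lungs at 11 weeks showed strong type 2, mucus, macrophage and neutrophil-attracting gene expression, together with plasma cell genes, and lower expression of NK cell and alveolar type 1 cell genes. Clca1, a secreted product of goblet cells (Gene ID 23844, chromosome 3, 145004537 to 145032776 on mm10), rose from 0.744 ± 1.19 to 408 ± 290 CPM. Mmp12, the macrophage elastase (Gene ID 17381, chromosome 9, 7344397 to 7360461), rose from 6.38 ± 2.37 to 941 ± 296 CPM. Ccl11, an attractant of eosinophils (Gene ID 20292, chromosome 11, 82057832 to 82062955), rose from 2.92 ± 3.17 to 90.8 ± 21.2 CPM. All 6 mice were above all 5 saline mice for these 3 genes. Of the 15979 genes, 1382 were higher and 1077 lower.

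Among type 2 cytokines and receptors, 6 of 13 measured genes rose at 11 weeks and 0 fell, and 7 rose and 1 fell when adjusted over the list alone. The list was higher with an adjusted p of 3.49e-05, or adjusted p = 0.0223 with an estimated correlation. Il13, the cytokine of goblet cell change, was counted 2 times over all saline mice and 535 times over the exposed mice, a ratio of 297 (95% interval 81.8 to 2460). Il5, the eosinophil growth factor, rose by 3.07 ± 0.85 on the log2 scale and Il1rl1, which encodes the IL-33 receptor, by 2.96. Il4 did not pass the count filter. Of the goblet cell and mucus list, 11 of 14 genes rose (adjusted p = 0.00178 with an estimated correlation), 13 when adjusted over the list alone. Next to Clca1 these included Itln1 (log2 fold change 5.97), the anion exchanger Slc26a4 (5.92), Fcgbp (4.45) and the gel-forming mucin Muc5ac (3.24).

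Of the alternatively activated macrophage list, 13 of 15 genes rose at 11 weeks (adjusted p = 0.000169 with an estimated correlation). Arg1, which encodes arginase (Gene ID 11846, chromosome 10, 24915207 to 24927470), rose by 6.51 ± 1.02 to 386 ± 221 CPM. Retnla, a secreted marker of these macrophages (Gene ID 57262, chromosome 16, 48842609 to 48844461), rose by 6.32 ± 0.58 to 4634 ± 1140 CPM. Chil3 rose by 5.16 and its close paralog Chil4 by 5.41, and short reads can be divided between these 2 genes. Without saline replicate 3, Arg1 rose by 7.88, Ccl11 by 5.89 and Chil4 by 9.66. The interstitial and monocyte-derived macrophage list held 6 genes that rose, with Gpnmb (5.40) and Trem2 (3.54) among them, and 1 that fell of 12 (adjusted p = 0.00178 with an estimated correlation). Type 17 and neutrophil-attracting mediators rose in 10 of 13 genes (adjusted p = 0.000956 with an estimated correlation), with Cxcl5 at 6.02, Cxcl1 at 4.30, Il6 at 4.40 and the iron-binding lipocalin Lcn2 at 3.89. Myeloid and T cell chemokines rose in 10 of 14 genes (adjusted p = 0.000765 with an estimated correlation), with Ccl7 at 4.23 and Ccl2 at 4.11 beside Ccl11.

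Plasma cell genes rose in 8 of 10 at 11 weeks (adjusted p = 0.00075 with an estimated correlation), including Derl3 (4.30), Jchain (3.96), which joins immunoglobulin chains, and Mzb1 (3.32). Extracellular matrix genes rose in 11 of 20 (adjusted p = 0.0185 with an estimated correlation), including Spp1 (6.32), Timp1 (4.72) and Tnc (2.77), and complement and acute phase genes in 5 of 13 (adjusted p = 0.027 with an estimated correlation). NK cell genes fell in 6 of 7 (adjusted p = 0.0223 with an estimated correlation), with Ncr1 at -2.42, Klre1 at -2.35 and the pore-forming Prf1 at -1.88. Alveolar type 1 genes fell in 6 of 9 (adjusted p = 0.0149 with an estimated correlation), with Hopx at -1.81 and Rtkn2 at -1.72. Of the 23 lists that passed at 11 weeks, 11 passed with an estimated correlation. Mast cell and basophil genes (4 of 11 higher, adjusted p = 0.239 with an estimated correlation) and cell cycle genes (8 of 12 higher, 0.154) were among those that did not. In the mast cell list the near-identical proteases Mcpt1 and Mcpt2 rose, Mcpt1 by 7.71 on the log2 scale and Mcpt2 from 3 counts over all saline mice to 863, a ratio of 319 (95% interval 109 to 1550), while Cpa3, a protease of most mast cells, was at 0.19 with an adjusted p of 0.92.

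Genes of fat and squamous epithelium varied between the saline mice. Adipose genes were lower at 11 weeks in 5 of 6 cases (adjusted p = 0.23 with an estimated correlation), and Adipoq, made by fat cells, was at 37.5 ± 72.0 CPM in saline. The largest falls, in Rptn (148 ± 326 CPM in saline) and Tgm3 (78.8 ± 171), which are genes of squamous epithelium, likewise rested on saline values whose SD exceeded the mean. Msx3, a homeobox gene (Gene ID 17703, chromosome 7, 140046157 to 140049088), was at 0 counts in saline and at 5.37 ± 2.11 CPM at 11 weeks, at least 219-fold higher.

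Exposure for 19 weeks was compared with saline to describe the chronic stage. Mucus, macrophage, neutrophil-attracting, plasma cell and extracellular matrix genes were higher, and NK cell and alveolar type 1 genes were lower. Npy, which encodes neuropeptide Y (Gene ID 109648, chromosome 6, 49822710 to 49829507), rose by 9.80 ± 0.96 on the log2 scale to 34.3 ± 13.9 CPM. Dlk1 rose by 9.25 ± 1.65, Clca1 by 7.30 ± 1.27 to 115 ± 106 CPM, and Mmp12 by 7.17 ± 0.75 to 917 ± 552 CPM. In all, 3072 genes were higher and 2490 lower, with mice of the 2 groups differing in GC slope by the means given above.

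Goblet cell and mucus genes rose in 13 of 14 at 19 weeks, type 17 and neutrophil-attracting mediators in 11 of 13, alternatively activated macrophage genes in 11 of 15, plasma cell genes in 9 of 10 and myeloid and T cell chemokines in 10 of 14, with Ccl5 lower (each adjusted p = 0.0166 with an estimated correlation). Examples were Slc26a4 (5.79), Fcgbp (4.73), Muc5b (3.33), Lcn2 (4.47), Cxcl5 (5.32), Retnla (5.70), Arg1 (5.63), Derl3 (4.61), Ccl11 (3.91) and Ccl2 (3.17). Il13 was 175 times its level in saline (95% interval 48.1 to 1450). Extracellular matrix genes rose in 16 of 20 (adjusted p = 0.0225 with an estimated correlation), among them Col1a1 (2.55), Eln (2.43), which encodes elastin, Tnc (2.81) and Timp1 (4.23), while Postn (-1.09) and Fap (-1.31) fell. NK cell genes fell in 6 of 7 (adjusted p = 0.025 with an estimated correlation), with Klre1 at -4.53 and Ncr1 at -3.21, and alveolar type 1 genes in 6 of 9 (adjusted p = 0.0342 with an estimated correlation), with Hopx at -2.19. Complement and acute phase genes rose in 6 of 13 (adjusted p = 0.0464 with an estimated correlation), including Orm1 (3.08).

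Several lists passed at 19 weeks with the preset correlation alone. Interferon response genes fell in 9 of 13, among them Gbp2 (-2.59), Ifng (-2.42) and Ifit3 (-2.06), with adjusted p = 0.116 with an estimated correlation. Endothelial genes fell in 5 of 11, such as Ednrb (-3.10) and Tek (-2.65), with adjusted p = 0.102 with an estimated correlation, and fibroblast genes in 5 of 10, such as Tcf21 (-2.28) and Inmt (-2.51), with adjusted p = 0.123 with an estimated correlation. Type 2 cytokines and receptors rose in 9 of 13 and Tslp fell (-1.73), with adjusted p = 0.147 with an estimated correlation. Alveolar type 2 genes rose in 6 of 10 (adjusted p = 0.163 with an estimated correlation), Napsa (1.44) among them. The eosinophil list did not pass, and its members moved apart: Prg2 rose by 1.84 while Ear1 was at -2.95 and Siglecf, also a marker of alveolar macrophages, at -1.32.

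Lungs at 19 and 11 weeks were compared with each other for change with time. Few genes differed, with 14 higher and 3 lower at 19 weeks, against 2296 genes at an unadjusted p under 0.05, where 799 would be expected if no gene differed. Dmbt1, an epithelial scavenger receptor of the goblet cell list, rose from 1.14 ± 0.519 to 8.00 ± 3.84 CPM (log2 fold change 2.80 ± 0.56, adjusted p = 0.0279). Ypel4 rose by 2.77 (adjusted p = 0.01), Pkhd1 by 2.57 and Fga, a fibrinogen chain, by 2.21, and Gc, which encodes the vitamin D binding protein, was also among the genes that rose. Aldh1a3, an enzyme of retinoic acid synthesis, fell by 2.12 ± 0.43 and Gpr183, a receptor that positions B cells, by 0.98. For cell cycle (7 of 12 genes lower when adjusted over the list alone), B cell (6 of 10) and interferon response genes (5 of 13), the list tests passed with preset p of 9.61e-08, 1.22e-05 and 3.32e-07, and each had an adjusted p = 0.222 with an estimated correlation. The count of 17 fell to 0 with the replicate number as a block or without 11-week replicate 8, and was 110 with DESeq2.

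The isotype group was compared with HDM alone at 19 weeks to see what the control antibody did. By edgeR 0 genes passed, while DESeq2 called 4 and limma voom with sample weights 1. An unadjusted p under 0.05 by edgeR was reached by 341 genes, fewer than the 799 expected if no gene differed. Ccl11 was at 40.8 ± 15.2 CPM with isotype and 44.4 ± 16.9 CPM without antibody. The lists for cell cycle, immediate early and alveolar macrophage genes passed with the preset correlation (0.0195, 0.0195 and 0.000177), with adjusted p = 0.919, 0.919 and 0.204 with an estimated correlation.

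Blocking IL-33 alone was compared with isotype. By edgeR 0 genes passed, 2878 had an unadjusted p under 0.05 and the lowest adjusted p was 0.246, while DESeq2 called 8 and limma voom with sample weights 1019. Of the type 2 list, 0 of 13 genes were called by edgeR, with a preset p of 0.0727 and adjusted p = 0.562 with an estimated correlation. Ccl11 differed by 0.01 on the log2 scale, and Clca1 was at 620 ± 661 CPM against 148 ± 241 CPM (log2 fold change 2.07 ± 0.86, adjusted p = 0.264). The goblet cell, ciliated, club and NK cell lists were higher and the extracellular matrix list lower with the preset correlation. Adjusted over the list alone, 8 of 14 goblet cell, 7 of 10 ciliated and 6 of 9 club cell genes were higher. Each of these 5 lists had an adjusted p = 0.549 with an estimated correlation. Leaving out anti-IL-33 replicate 7 gave 137 genes.

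Blocking IL-4Rα alone was also compared with isotype. By edgeR 0 genes passed, 2242 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0826, while DESeq2 called 13 and limma voom with sample weights 12. The erythroid list was higher, with 7 of 7 genes when adjusted over the list alone, and Slc4a1, the red cell anion exchanger, was at 97.2 ± 222 CPM against 1.95 ± 1.57 CPM (adjusted p = 0.0826). The list had an adjusted p = 0.982 with an estimated correlation, as did the mitochondrially encoded list. Ccl11 was at -0.44 and Arg1 at 0.32 on the log2 scale relative to isotype, with adjusted p above the threshold. Leaving out anti-IL-4Rα replicate 7 gave 13 genes. In simulated data for these 2 contrasts, 84% and 94% of 4-fold changes but 35.4% and 24% of 2-fold changes were recovered on 15864 and 15884 genes. The simulated libraries held no differences in GC slope. These shares therefore cannot say which changes would have been missed in the real libraries.

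Both antibodies together were compared with isotype. Ccl11, Arg1 and Retnla were lower, as were 9 of 20 extracellular matrix genes, and ciliated, club, adipose and mitochondrially encoded genes were higher as lists with the preset correlation. These 4 lists and the matrix list each had an adjusted p = 0.501 with an estimated correlation. Ccl11 fell from 40.8 ± 15.2 to 5.33 ± 2.21 CPM (log2 fold change -2.94 ± 0.48, adjusted p = 0.00122). Arg1 fell from 242 ± 238 to 10.8 ± 5.10 CPM (-4.48 ± 0.92, adjusted p = 0.00549). All 5 combination mice were below all 7 isotype mice for both genes. Retnla fell from 2850 ± 1637 to 614 ± 291 CPM (-2.21, adjusted p = 0.0059), with 5 of 5 mice below the isotype mean. In all, 2019 genes were higher and 1010 lower, of which 1580 and 582 by at least 2-fold.

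Of the 1010 genes that fell with the combination, 364 were among the 3072 raised by 19 weeks of HDM. A further 351 of those 3072 rose, and of the 2490 genes lowered by HDM 278 rose and 22 fell. Over all 15979 genes, 2019 rose and 1010 fell. The share of raised genes that fell was above that over all genes. The shares that rose, 351 of 3072 and 278 of 2490, were slightly below that over all genes. The 278 rises alone therefore do not show a reversal. Of the genes raised by HDM, the numbers lowered and raised further were 414 and 553 with DESeq2 and 615 and 206 with GC and length offsets. They were 451 and 66 with the GC slope as a covariate and 132 and 20 without the steep libraries. The median log2 fold change of the 3072 genes with the combination was 0.23, and 40% of them had a negative value. These values were 0.277 and 38.1% with DESeq2, but -0.143 and 59.9% with GC and length offsets. With the GC slope as a covariate they were -0.175 and 67.3%, and without the steep libraries -0.413 and 82.1%. Of the type 2 list, Il13ra2, the decoy receptor of IL-13 (-3.55, adjusted p = 0.00751), and Il1rl1 (-2.03, adjusted p = 0.0173) fell, while Il13 was at -0.77 with an adjusted p of 0.243. Of the alternatively activated macrophage list, 5 of 15 genes fell (Arg1, Retnla, Chil4 at -2.91, Ccl24 at -3.21 and Pdcd1lg2 at -1.72), and Ccl17 (1.35) and Ccl22 (0.74) rose. These 2 lists did not pass as lists (adjusted p = 0.0588 and 0.157). Of the goblet cell list, Clca1 (-2.75, adjusted p = 0.0467) and Slc26a4 (-1.97) fell, whereas Muc5b (1.26), Agr2 (1.77), Dmbt1 (1.58) and Spdef (1.34) rose and Muc5ac was at -0.65 with an adjusted p of 0.291. Of the myeloid and T cell chemokines, Ccl11, Ccl9 (-1.98), Ccl4 (-1.44) and Cxcl12 (-0.90) fell and Ccl6 (1.58) rose.

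Extracellular matrix genes fell in 9 of 20 with the combination and 0 rose, with 10 lower and 2 higher when adjusted over the list alone. Fn1, which encodes fibronectin, fell by 1.85 ± 0.49, Tnc by 1.84, Mmp12 by 2.17, Timp1 by 1.57, Ccn2 by 1.41 and Col5a2 by 1.17, while Col1a1 was at 0.29 and Postn at 0.02. The list had a preset adjusted p of 0.0204, and adjusted p = 0.501 with an estimated correlation. Its preset p was 0.0638 without isotype replicate 4, 0.161 without combination replicate 2 and 0.0994 without combination replicate 3. It passed, still lower, with GC and length offsets (0.0206), with the replicate block (0.00509) and with fry (0.0112). Without the steep libraries, which leaves combination replicates 2 and 3, its preset p was 1.06e-06. The group 2 innate lymphoid cell list also fell (preset p 0.0204, adjusted p = 0.501 with an estimated correlation), with Arg1 and Il1rl1 as its 2 called members of 9, and Arg1 is also abundant in macrophages. That list's preset p was 0.0773 without combination replicate 5, 0.0565 with GC and length offsets and 0.877 without the steep libraries.

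Ciliated cell genes rose in 7 of 10 with the combination, Foxj1, the regulator of motile cilia (2.48), and Tppp3 (2.21) among them, and club cell genes in 5 of 9, such as Scgb3a2 (2.95) and Scgb3a1 (2.40). Mitochondrially encoded genes rose in 15 of 20, with ND2 at 8005 ± 8778 against 1649 ± 502 CPM. Mitochondrial genes took 22.7% of counts in combination replicate 2, 13.4% in replicate 1 and 3.85% to 5.28% in the other 3, against 2.51% to 6.34% with isotype. ND2 was at 2.28 with all libraries, 1.49 without combination replicate 2 and 2.07 without replicate 1, where it was no longer called (adjusted p = 0.0654). Adipose genes rose in 5 of 6, with Plin1 at 19.3 ± 24.9 against 0.798 ± 0.325 CPM and Adipoq at 17.5 ± 20.2 against 1.19 ± 0.751 CPM. NK cell genes rose in 2 of 7. The preset p of these 5 lists lay between 5.81e-06 and 0.0382, and they had an adjusted p = 0.501 with an estimated correlation, or 0.521 for NK cells. Without combination replicate 2, the list p was 0.158 for club and for NK cells. That of NK cells was also 0.0646 and 0.0989 without isotype replicates 1 and 4, 0.0601 without combination replicate 3, 0.0518 with fry and 0.13 without the steep libraries, where that of adipose genes was 0.0651. Without the 10 steep libraries, which leaves combination replicates 2 and 3, Foxj1 was at 0.54, Tppp3 at 0.97 and Plin1 at 1.10 and these 3 were no longer called, while ND2 was at 2.80 and Fabp1, a fatty acid binding protein (4.69 with all libraries), at 4.12 and both were called. Among the largest rises, BC018473 (6.97 ± 1.70) was at -0.03 when the 19-week mice without antibody served as the control.

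The call count of the combination depended on single mice and moved with the settings. It was 207 without combination replicate 1, 7899 without combination replicate 2, 551 with the replicate number as a block and 686 without the steep libraries, and another split of the same mice called 7701. The fit without the steep libraries also drops mice. With all mice kept, the count was 3792 with GC and length offsets and 2010 with the GC slope as a covariate. Of the 41 named genes called in this contrast, 5 were called under all 16 alternatives and in all 12 fits that left out 1 mouse: Ccl11, Arg1, Retnla, Msx3 (-4.53) and Fabp1.

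**Figure D2:**
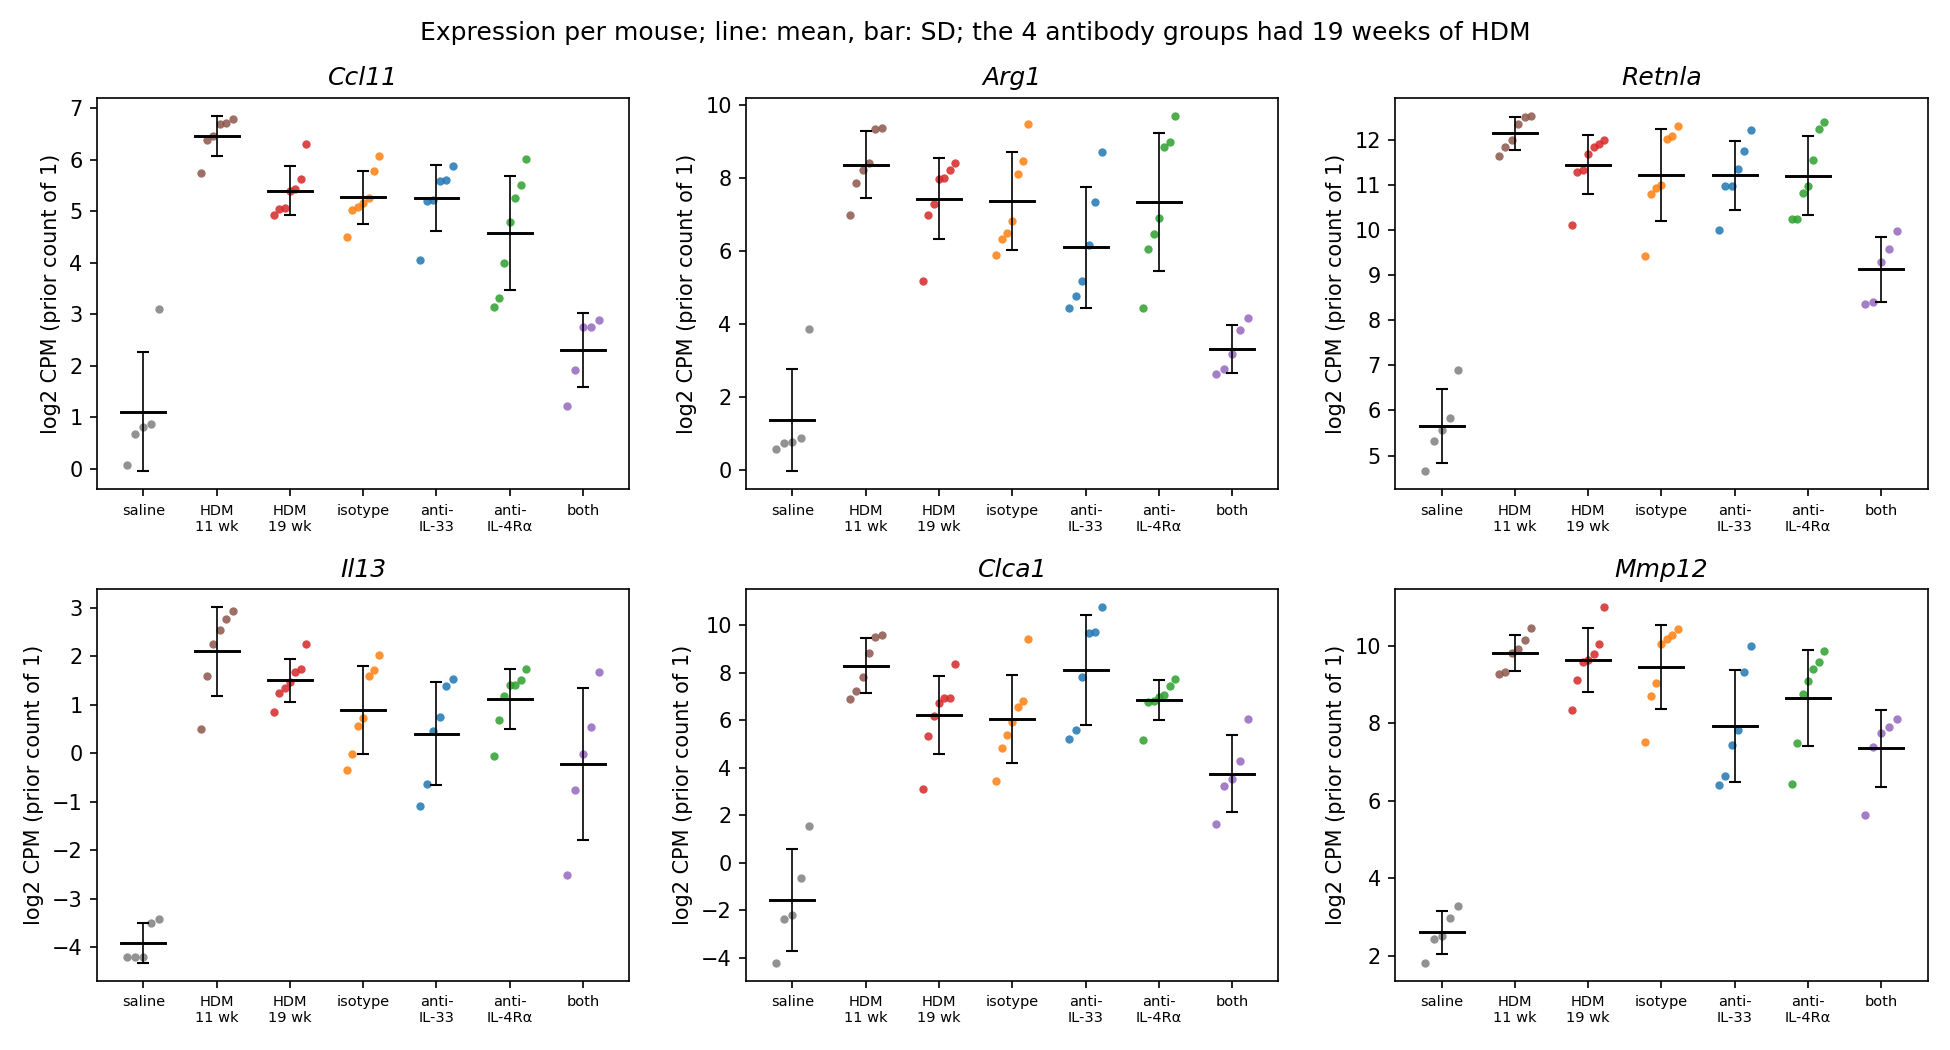
Log2 CPM of 6 genes in each mouse by group; points are mice, lines means and bars SD. Ccl11 and Arg1 lie lower in all 5 combination mice than in all 7 isotype mice, while Il13 differs from isotype by a log2 fold change of -0.77.

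The combination was compared with each single antibody. Against anti-IL-33, 0 genes were higher and 7 lower: Rnase2a, an eosinophil-associated ribonuclease (Gene ID 93726, chromosome 14, 51255261 to 51256112; 1.59 ± 1.41 against 35.7 ± 12.1 CPM, adjusted p = 0.0105), Cd209e (-3.99), Msx3 (-3.77), Col6a5 (-3.74), Ptgdr (-3.64), Ccl11 (-2.95, adjusted p = 0.00714) and Aldh1a3. Against anti-IL-4Rα, 16 genes were lower, among them Arg1 (-4.80, adjusted p = 0.0191), Fbp1 (-3.92), Msx3 (-3.91), Ccl11 (-2.51, adjusted p = 0.0191) and Retnla (-2.17, adjusted p = 0.0334), and 3 were higher, Xkrx (7.29), Kctd8 (2.17) and Vnn1 (2.08). All 5 combination mice lay below every mouse of both single-antibody groups for Ccl11, Arg1 and Retnla. The alternatively activated macrophage list was lower than with anti-IL-33 (preset p 3.36e-08, adjusted p = 0.0144 with an estimated correlation), with 5 of 15 genes lower when adjusted over the list alone. It was lower than with anti-IL-4Rα with a preset p of 0.00298 and adjusted p = 0.212 with an estimated correlation. Without combination replicate 3 the counts were 0 and 1, and without anti-IL-4Rα replicate 2 the latter was 583; with the replicate number as a block they were 5 and 0. Other splits of the same mice called up to 10178 and 10452 genes.

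The 2 single antibodies were compared with each other, and by edgeR 0 genes passed, with 409 at an unadjusted p under 0.05, 3 genes by DESeq2 and 731 by limma voom with sample weights. Of 13 lists that passed with the preset correlation, all had an adjusted p between 0.183 and 0.433 with an estimated correlation. The interaction asked whether the combination differed from the sum of the single antibody effects. By edgeR 0 genes passed (321 at an unadjusted p under 0.05, lowest adjusted p 0.718), with 4 by DESeq2 and 5525 by limma voom with sample weights. Ccl11 was at -2.51 (adjusted p = 0.718) and Arg1 at -3.83 in this contrast. As a list, alternatively activated macrophage genes were below the sum (preset p 6.44e-09, adjusted p = 0.00946 with an estimated correlation; fry 0.109) and tuft cell genes above it (preset p 0.00709, adjusted p = 0.0367 with an estimated correlation; fry 0.168), with 4 of 15 and 0 of 6 members called when adjusted over the list alone.

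The HDM score of each mouse, planned as the summary of reversal, gave no difference between antibody groups that passed with the genes and scaling planned. Means were 89.2 ± 21.2 (SD) with isotype, 91.0 ± 31.3 with anti-IL-33, 99.2 ± 17.2 with anti-IL-4Rα and 85.1 ± 31.2 with the combination, on a scale of 0 for saline and 100 for 19 weeks of HDM, where 11 weeks of HDM scored 70.4 ± 13.5. The combination differed from isotype by -4.1 (exact permutation p = 0.802), and all 6 comparisons had an adjusted p of 0.883. With the genes called at 11 weeks in place of those at 19 weeks, the difference was -22.7 (adjusted p = 0.0378). With the 19-week genes it was -23.9 with GC and length offsets (exact permutation p = 0.0227, adjusted 0.0681), -40.1 without the steep libraries (exact permutation p = 0.0833, adjusted 0.25) and 7.3 without combination replicate 2. The combination differed from anti-IL-4Rα by -14.1, and by -21.7 with offsets (exact permutation p = 0.00505, adjusted 0.0303) and -19.9 with the 11-week genes (adjusted p = 0.0152), which both passed; without combination replicate 2 it was -2.7.

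**Figure D3:**
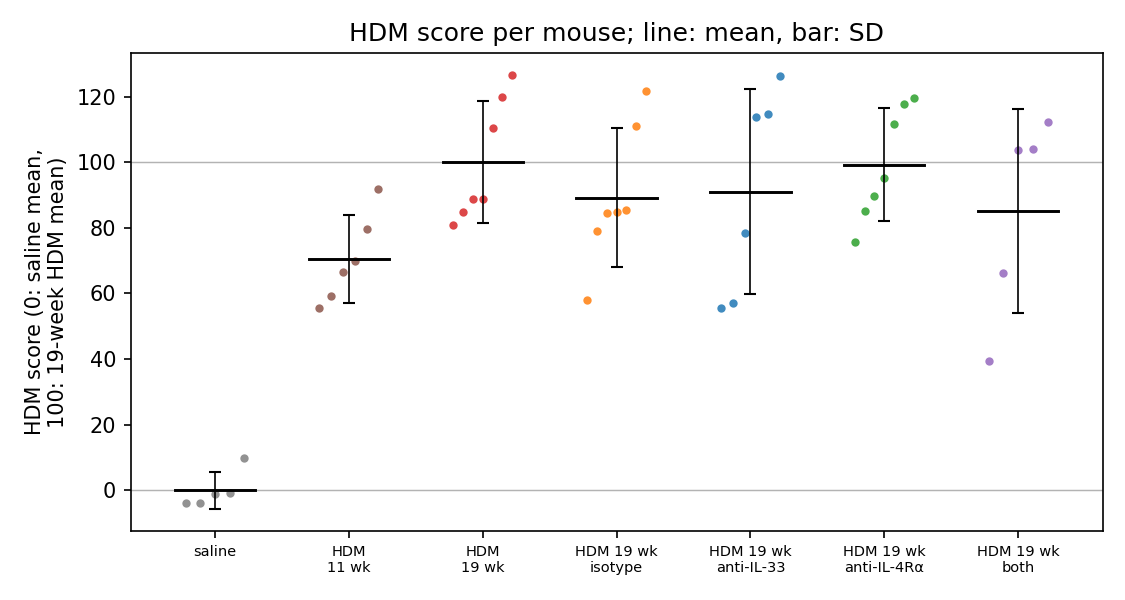
HDM score of each mouse by group, with 0 at the saline mean and 100 at the mean of 19 weeks of HDM; points are mice, lines means and bars SD. The combination mice range from 39.5 to 112.3.

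Every antibody group was also compared with saline, and all 4 differed from it widely. Isotype differed in 2073 genes higher and 1977 lower, anti-IL-33 in 4026 and 2853, anti-IL-4Rα in 4138 and 2978, and the combination in 4441 and 3240. Mean GC slopes also differed from saline, by 0.469, 0.933, 0.901 and 1.02 in that order. The sizes of these counts therefore cannot be read as effects of treatment alone. Counts that changed under settings for GC slope are given below. With the combination, type 17 and neutrophil-attracting mediators were higher than in saline in 11 of 13 genes, goblet cell genes in 13 of 14 and plasma cell genes in 6 of 10 (adjusted p = 0.0591, 0.084 and 0.0909 with an estimated correlation), with Lcn2 at 5.24 ± 0.29, Cxcl5 at 5.42, Saa3 at 6.50, Jchain at 4.46, Retnla at 3.41 and Mmp12 at 4.89. Differences from saline did not pass for Ccl11 (0.85 ± 0.48, adjusted p = 0.14), Arg1 (1.35 ± 0.84, adjusted p = 0.17), Chil4 (0.93) and Il1rl1 (0.26), which with isotype lay 3.79, 5.83, 3.84 and 2.29 above saline and passed there. Saline replicate 3 stood above the other saline mice for Ccl11, Arg1 and Chil4, and without it the combination lay 1.78 (adjusted p = 0.00302), 2.71 (0.0149) and 5.19 (0.000447) above saline and passed.

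The fold changes of the 2 single antibodies against the shared isotype mice correlated across genes at r = 0.812 with a covariance of 0.222, where simulated unchanged groups gave 0.467 and 0.068. The simulated libraries held no differences in GC slope, so these values can be too low for unchanged groups of the real libraries. With the isotype mice split so that each response had its own controls, the mean covariance over 35 splits was 0.185. Without the steep libraries the correlation was 0.191 and the covariance 0.0217. Genes are not independent replicates, and by edgeR no gene was called in both responses, with 0 called in either. DESeq2 called 8 with anti-IL-33 and 13 with anti-IL-4Rα, and limma voom with sample weights 1019 and 12. The overlap of those calls was not counted.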

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

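Chosen after the results were seen were both tests that leave out single mice, both tests on the covariance of the antibody responses, the limit that defines steep libraries and the comparison of GC slopes between splits. The criteria for the prediction of shifts from GC slope and for the splits of the mice were set before those tests were run. The gene sets of the prediction were taken from the calls themselves. In 161 tests for a mouse far from the others of its group, 12 stood out, where chance gives about 8. Saline replicate 3 stood above the other saline mice for Ccl11 (log2 CPM 3.11, next mouse 0.87), Chil4 (4.69, next -0.65), Arg1 (3.87, next 0.87) and the HDM score (9.81, next -0.72). Among the 19-week mice, replicate 6 was low for Muc5ac (1.26, next 2.95) and replicate 7 for Retnla (10.1, next 11.29). With anti-IL-33, replicate 5 was low for Ccl11 (4.06, next 5.21) and replicate 4 high for Il6 (3.1, next 1). With anti-IL-4Rα, replicate 4 was low for Clca1 (5.15, next 6.78), replicate 2 was low for Siglecf (-0.02, next 2.19) and high for Jchain (12.59, next 11.25), and replicate 8 had a total count of 21.25 M (next 16.85 M).

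Differences between groups tested directly gave 17 genes between 19 and 11 weeks of HDM, 7 between the combination and anti-IL-33 and 19 between the combination and anti-IL-4Rα. Each count was set against 100 splits of the same mice into groups of the same sizes, the real one included. No other split called as many genes as the real groups for 11 weeks (2459 genes, highest other split 546) and 19 weeks of HDM against saline (5562, 860). The same held for 19 against 11 weeks (17, highest other 0), and for isotype (4050, 1017), anti-IL-33 (6879, 6016) and anti-IL-4Rα (7116, 4397) against saline. In each, 1 of 100 splits was as large, the real one itself. That is the lowest rank that 100 splits can give, and it was not adjusted over the contrasts. It counts against chance for these contrasts without excluding it. These splits cannot separate treatment from GC slope. The real groups differed from saline in slope by 0.765 at 19 weeks, 0.469 with isotype and 0.933 with anti-IL-33. The highest differences in other splits were 0.758, 0.469 and 0.931. At 11 weeks and with anti-IL-4Rα the real differences were 0.237 and 0.901, and the highest others 0.307 and 0.969. For the combination, 3 of 100 splits were as large against isotype (3029 genes) and 2 of 100 against saline (7681), the real one included. These ranks were not adjusted over the contrasts split in this way. Splits there also reached 7701 and 9237 genes, which points to a structure of the mice other than treatment. Chance is therefore left open for both counts. Chance also stays open for the combination against anti-IL-33 (7 genes, 19 of 100 splits as large, highest other 10178) and against anti-IL-4Rα (19 genes, 13 of 100, highest other 10452). Other splits there called many times the real count, which again points to such a structure. The splits that called at least as many genes differed more in GC slope at the median, by 0.944 for the combination and isotype mice, 0.795 with anti-IL-33 and 0.800 with anti-IL-4Rα, against 0.322, 0.318 and 0.338 over all splits but the real one and 0.552, 0.088 and 0.119 for the real groups. In some of these splits with the single antibodies the difference was small, at lowest 0.180 and 0.219. For the counts of 0 by edgeR, all 100 splits were as large, which any count is, and the highest other split gave 1 gene for isotype against HDM, 19 for anti-IL-33 and 1734 for anti-IL-4Rα against isotype, 8246 between the single antibodies and 4689 for the interaction.

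The first pattern weighed is the change with the combination against isotype. Library quality was tested by predicting each gene's shift from its regression on GC slope in the 14 mice with HDM alone or isotype. The prediction gave -0.4% of the median observed shift for the 364 lowered genes that HDM had raised, 11.4% for the 646 other lowered genes and 44.2% for the 2019 raised genes. At the median, this argues against a linear effect of GC slope as the cause of the falls. The regression mice had slopes from -0.47 to 0.857 and the combination mice from -1.037 to 1.115, so the prediction reached beyond them. Without the steep libraries, which removes 3 combination mice, 207 genes were called lower, against 1010 with all. For the rises quality and treatment cannot be told apart, since 42.8% of these genes were predicted by at least 50% of their shift. Since other splits also gave as many genes, chance stays open for the number of calls. An effect of blocking both pathways on the lowered genes stays open as a hypothesis, found and tested on the same mice.

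The second pattern is the lower expression with the combination than with anti-IL-33 (7 genes) or anti-IL-4Rα (16 genes). The same prediction, with the same limit of range, gave 0.3% of the median shift over these 23 differences. Mean GC slopes differed by 0.088 (anti-IL-33) and 0.119 (anti-IL-4Rα) from the combination, so a linear effect of the mean slope had little room. A share near 0 was therefore all but fixed in advance, and the prediction says nothing more on these genes. Whether the genes were called rested on single mice: 0 of them stayed called without combination replicate 3, and 0 without replicate 5. A test of the size of the shift was added once that was seen. Leaving out 1 mouse at a time kept at least 94.2% of the median shift (-3.53 against -3.74 for anti-IL-33, without combination replicate 5). The genes had been chosen for being called with all these mice, so that test could hardly have come out otherwise. It does not decide whether 1 mouse carried the fold. Since other splits also gave as many genes, chance stays open for the calls, as does an effect of the second antibody, which was not tested on other mice.

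The third pattern is that the fold changes of anti-IL-33 and anti-IL-4Rα against isotype moved together (covariance 0.222, simulated unchanged groups 0.068). Shared isotype mice do not account for it alone, since split isotype libraries gave a mean of 0.185 and at lowest 0.127. The simulated libraries held no differences in GC slope, so 0.068 is not a full baseline for unchanged groups of the real libraries. Without the steep libraries, 9.8% of the covariance was left, but with GC and length offsets and all mice kept it was 0.131, so library quality is a candidate explanation for part of it. A shared effect of the antibodies was not separately tested and stays open.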

How the results depend on the processing

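The GC and length offsets, the GC slope as a covariate, the fits without the 10 steep libraries and the fit without 1 gene ID were chosen after the data were seen; the other settings and the left-out libraries were fixed before. Across all settings and left-out libraries, 302 counts of called genes stayed within 1.5 times the reported count and 109 did not. Of the list tests, 7242 kept their side of the threshold, 348 newly passed, 351 no longer passed and 4 turned. Of the values of named genes, 16841 kept their side, 356 newly passed, 532 no longer passed and 8 turned. A turn was counted only where the result passed in the reported fit or in the alternative. Changes of sign in results that passed in neither were not counted. Upper-quartile factors, DESeq2 size factors in edgeR, the stricter filter and the fit without 1 gene ID moved none of the 15 counts by over 1.5 times. The cause of the changes below was not tested, except that leaving out libraries removes mice and the fits of the compared groups alone estimate the spread from fewer mice. Sample weights in limma voom ran from 0.0807 (combination replicate 2) to 5.77 (saline replicate 4).

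Below, HDM stands for HDM without antibody, and each number is a count of genes past the threshold, with the reported count first. HDM at 11 weeks against saline (2459) gave 4150 with GC and length offsets, 5873 without the steep libraries, 4635 with the GC slope as a covariate, 6670 with offsets and without the steep libraries, 8618 with limma voom and 6038 with these groups alone. At 19 weeks against saline (5562) limma voom gave 10325. HDM at 19 against 11 weeks (17) gave 11 without a filter, 0 with the replicate block, 129 with the library number block, 26 with the GC slope as a covariate, 26 with offsets and without the steep libraries, 305 with limma voom, 110 with DESeq2 and 68 with these groups alone. Isotype against HDM (0) gave 1 with limma voom and 4 with DESeq2. Anti-IL-33 against isotype (0) gave 3 with the library number block, 1019 with limma voom, 8 with DESeq2 and 15 against HDM and isotype pooled. Anti-IL-4Rα against isotype (0) gave 12 with limma voom, 13 with DESeq2, 1 with these groups alone and 14 against the pooled control. All saline, 11-week HDM and anti-IL-4Rα libraries lay in the earlier library number block, and all 19-week HDM and isotype libraries in the later one. Only anti-IL-33 and the combination had libraries in both, and the block effect was estimated from these alone. Contrasts between groups of different blocks, such as 19 against 11 weeks, do not separate group from library number. The counts with this block are therefore no independent check of them.

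The combination against isotype (3029) gave 551 with the replicate block, 1318 with the library number block, 686 without the steep libraries, 2010 with the GC slope as a covariate, 844 with offsets and without the steep libraries, 9262 with limma voom, 1824 with these groups alone and 1325 against HDM. Higher and lower calls were 2019 and 1010 as reported and 783 and 1227 with the GC slope as a covariate. Against anti-IL-33 (7) the combination gave 123 without the steep libraries, 128 with offsets added, 7801 with limma voom, 21 with DESeq2 and 1 with these groups alone. Against anti-IL-4Rα (19) it gave 0 with the replicate block, 1 with the library number block, 101 with offsets, 43 without the steep libraries, 520 with the GC slope as a covariate, 166 with offsets and without the steep libraries, 8510 with limma voom, 151 with DESeq2 and 0 with these groups alone. The single antibodies against each other (0) gave 731 with limma voom, 3 with DESeq2 and 1 with these groups alone. The interaction (0) gave 2 with the replicate block, 3 without the steep libraries, 1 with the GC slope as a covariate, 8 with offsets and without the steep libraries, 5525 with limma voom and 4 with DESeq2. Against saline, isotype (4050) gave 8360 without the steep libraries, 8341 with offsets added, 10517 with limma voom and 8078 with these groups alone; anti-IL-33 (6879) gave 3769 with the GC slope as a covariate; the combination (7681) gave 2912 without the steep libraries, 3831 with the GC slope as a covariate, 4163 with offsets and without the steep libraries and 4845 with these groups alone.

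Replicate numbers did not pair the mice: deviations from the group means correlated at -0.027 on average for the same number and 0.006 for different numbers, and 5 of 43 libraries correlated best with their own number in another group. Besides the counts given above, the replicate block moved the number of HDM genes called the opposite way with the combination from 642 to 288, and a call lost under it is not read as a weaker effect.

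Leaving out single libraries moved counts in these ranges. The combination against isotype ran from 207 without combination replicate 1 to 7899 without combination replicate 2, and it was 468 and 4883 without combination replicates 8 and 3, and 1504, 1451, 1336 and 1532 without isotype replicates 1, 2, 3 and 8. Against anti-IL-33 it ran from 0 (without combination replicates 3 or 5) to 10 (without anti-IL-33 replicate 4), with 1, 3 and 2 without combination replicates 1, 2 and 8, and 2, 4, 4 and 4 without anti-IL-33 replicates 2, 3, 6 and 7. Against anti-IL-4Rα it ran from 1 (without combination replicates 3 or 5) to 583 (without anti-IL-4Rα replicate 2), with 7 without combination replicate 1 and 11 without anti-IL-4Rα replicate 3. HDM at 19 against 11 weeks ran from 0 (without 11-week replicate 8) to 46 (without 19-week replicate 9). It was 1, 3, 7, 3 and 3 without 11-week replicates 1, 2, 3, 4 and 9, and 6, 5, 7 and 2 without 19-week replicates 1, 2, 5 and 7. Anti-IL-33 against isotype ran from 0 to 137 (without anti-IL-33 replicate 7) and was 5 without isotype replicate 9. Anti-IL-4Rα against isotype ran from 0 to 13 (without replicate 7), with 11, 5, 10 and 9 without replicates 3, 4, 5 and 8. The single antibodies against each other ran from 0 to 1 (without anti-IL-33 replicate 7) and the interaction from 0 to 1 (without isotype replicate 6). Against saline, anti-IL-33 ran from 4451 (without replicate 4) to 7582 (without replicate 3) and the combination from 4854 (without replicate 1) to 10018 (without replicate 2). The 642 HDM genes called the opposite way with the combination ran from 141 (without combination replicate 1) to 817 (without combination replicate 2), with 210 without combination replicate 8 and 395 without isotype replicate 1.

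That number was 1117 with offsets, 295 without the steep libraries and 302 with both. The score difference of the combination from isotype became -22.7 with the genes called at 11 weeks and passed, -23.9 with offsets and -40.1 without the steep libraries, and that from anti-IL-4Rα -19.9 with those genes and -21.7 with offsets, which both passed. The covariance of the single-antibody responses (0.2216) became 0.1853 with split isotype libraries, 0.1305 and 0.1265 with HDM as the control of either response, 0.131 with offsets and 0.0217 without the steep libraries. For anti-IL-33 and the combination (0.4093) these were 0.373, 0.3182, 0.3018, 0.2592 and 0.1, and for anti-IL-4Rα and the combination (0.3115) 0.2752, 0.2164, 0.204, 0.1938 and 0.0728.

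Directions turned in 12 cases, counted only where the result passed in the reported fit or in the alternative. BC018473, combination against isotype, was at -0.029 against HDM. With limma voom Il5 was at -2.73 against isotype and -3.01 against anti-IL-4Rα, Il2ra at -1.64, Il4ra at 1.01 and Il33 at -1.47 against anti-IL-33, and Ltc4s at 1.26 and Il33 at -1.77 in the interaction. With offsets and without the steep libraries, list tests turned for immediate early genes between 19 and 11 weeks (p 0.0103), ciliated genes in the interaction (0.0357) and mitochondrially encoded genes with anti-IL-33 (0.0161, and 0.00593 without offsets). Of the 41 named genes called for the combination against isotype, 13 were not called with the replicate block, 25 without the steep libraries and 9 with the GC slope as a covariate. Epx had too few counts to test, and Il4, with a highest count of 1, was replaced by human sequence in the mice used to assess the antibodies, so its count says nothing on depth there. The alternative without immunoglobulin genes was not run, since the symbol pattern matched no immunoglobulin gene in the table.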

Other observations

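No test of an explanation is added here; the values of genes outside the comparison that named them were picked after they were seen. Among the largest falls with the combination, A2m, Fgf23 and Dlk1 were genes that HDM had raised. A2m, a protease inhibitor, was at 0.391 ± 0.421 CPM (SD, n = 5) in saline, 21.9 ± 13.2 CPM (n = 7) after 19 weeks of HDM, 26.1 ± 23.2 CPM (n = 7) with isotype and 0.484 ± 0.393 CPM (n = 5) with the combination (edgeR adjusted p = 0.00711 against isotype). Fgf23, a phosphate-regulating hormone best known from bone, was at 0.0450 ± 0.0565, 16.0 ± 17.9, 13.4 ± 8.76 and 0.464 ± 0.345 CPM in the same groups (adjusted p = 0.00526). Dlk1, a Notch-like membrane protein, fell by 5.28 ± 1.36 on the log2 scale against isotype after a rise of 9.25 with HDM. Guca2a, a guanylate cyclase activator, was counted 3 times over the combination mice and 146 times over the isotype mice, a ratio of 25.4 (95% interval 8.53 to 125).

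Fibroblast genes split with the combination: 6 of 10 rose, among them Lum (2.01), Col13a1 (1.89), Inmt (1.71) and Dcn (1.42), and Col14a1 fell (-2.28), with a list p of 0.0578 and adjusted p = 0.501 with an estimated correlation. Eosinophil genes gave 0 calls of 7 by edgeR for the combination against isotype, with a list p of 0.939, and Siglecf at -0.24. Plasma cell genes had 1 call of 10, Pou2af1 (-0.96), and Jchain was at 0.74 with an adjusted p of 0.269. Among interferon response genes, Cxcl9 (1.78) and Ifit3 (0.99) rose and 11 of 13 were not called.

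A single gene ID, which has no symbol in the annotation used, took between 0.341% of counts in a combination library and 23.4% in an anti-IL-4Rα library. Group means were 2.17 ± 0.62% in saline, 3.16 ± 1.29% after 11 and 8.86 ± 4.80% after 19 weeks of HDM, 6.33 ± 3.69% with isotype, 8.61 ± 6.49% with anti-IL-33, 13.8 ± 8.12% with anti-IL-4Rα and 7.21 ± 5.08% with the combination. Leaving it out gave 2725 called genes for the combination against isotype, where 3029 were called with it.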
